A study of Rattus norvegicus with 3 samples.

How the data were processed

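Single-nucleus RNA was measured in spinal cord of Sprague Dawley rats, 17 weeks old, with the lesion epicenter taken 49 days after spinal cord injury. There were 3 libraries and 1 library per group: untreated injured cord, cord with an implanted scaffold, and cord with a scaffold that releases hepatocyte growth factor (HGF), both implants having been in place for 7 days. Groups were taken from the treatment label of each sample. The labels do not say how many animals went into a library.

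Per the labels' protocols, nuclei were isolated with a commercial kit for neuronal tissue, captured in droplets with 10x Genomics 3′ gel beads, and sequenced as 150 bp paired-end reads. The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and nucleus, not normalized, made by the authors with Cell Ranger 6.0.1 per the submitters' processing notes and the file headers. The genome build and annotation were not given in the sources used here, and the gene lists of the files give symbols only, so no coordinates are reported. Each matrix holds 17328 genes, of which 2834 have no UMI in any library. The lowest nucleus of each library holds 500, 500 and 501 UMIs in the untreated, scaffold and HGF scaffold libraries, so the barcodes had passed a floor on UMIs before deposit. Older symbols were matched through a RefSeq gene table, used for names alone, and 640 of the 686 gene list entries were found in the files.

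Nuclei with at least 200 genes, at most 5% mitochondrial UMIs and no doublet call were kept, 5306 of 5326. The mitochondrial limit removed 4 nuclei, all untreated. Doublets were called with Scrublet in each library alone, at an expected rate of 0.8% per 1000 nuclei. It called 16 nuclei (0, 1 and 15 in the untreated, scaffold and HGF scaffold libraries), 0.300% of all, against expected shares of 1.80%, 1.73% and 0.725%. The calls were too few in the untreated and scaffold libraries and more than expected in the HGF scaffold library, so the removal fell almost wholly on that library. The planned removal was kept, and doublets were weighed by 2 other settings chosen after seeing the data: removal of the nuclei with the highest Scrublet scores at 2 times the expected rate, and removal of nuclei with at least 3 markers of at least 5 of 7 lineages (247, 311 and 42 nuclei).

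The 3 libraries were clustered together without integration in scanpy 1.11.5 under Python 3.11.15, with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and leidenalg 0.10.2. Counts were scaled to 10000 per nucleus and logged, 2000 variable genes and 30 principal components were taken, and Leiden clustering with 15 neighbours at resolution 1 gave 20 clusters. A cluster took the class of the marker list, out of 18 fixed before the data were examined, with the most genes among its leading genes. The details of that rule were set after seeing the data. Leading genes were the top 100 by fold over the median of the other clusters' means, because a shorter list ranked against all other nuclei left myeloid clusters unnamed. The committed oligodendrocyte precursor markers were joined to those of oligodendrocyte precursor cells (OPC). A cluster stayed unnamed with under 3 markers, with a tie, with more markers of another class among its top 10 genes, or with mixed markers and over 2 times its libraries' median UMIs. These rules left 4 clusters unnamed, whose shares per library are given with the results. No cluster took the ependymal, B or plasma cell, neutrophil, mast cell, adipocyte or erythroid name.

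Counts were summed per library and class and scaled by the summed UMIs of that library and class to CPM. Ratios carry exact conditional Clopper-Pearson intervals at 95%, CPM values exact Poisson intervals and shares exact Clopper-Pearson binomial intervals. All of them cover counting error only. With 1 library per group no test between groups exists, and no p-value is given. A ratio against 0 UMIs was computed against a floor of 3 counts per library and class and is written as a bound. That bound leaves out the counting error of the other library, so the exact interval of such a ratio reaches closer to 1. For each of 32 gene lists fixed before the data were examined, the median log2 CPM ratio of members with at least 20 UMIs in both libraries together was taken, minus the median of all genes past that minimum. Members are counted as higher or lower against that median of all genes. The list median was placed among those of 10000 random lists of the same size matched on mean expression. Its interval comes from 1000 Poisson resamples. A list with a percentile outside the middle 95% of random lists is said to stand apart, which describes these libraries and not the conditions. Lists planned for a class with under 50 nuclei in either library were read in all nuclei. The sex-linked list had 2 of 6 genes in the files and could not be measured. Some genes belong to more than 1 list, among them Tnc, Vegfa, Junb, Gfap and Cd86.

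Named genes were chosen by a rule fixed before the data were examined. It took Hgf and Met, and then, for scaffold over untreated and HGF scaffold over scaffold, the 3 higher and 3 lower genes with the largest conservative fold, the bound of the interval nearest 1, in each of the 4 classes with the most nuclei, counted in whichever library had fewer of them. Such genes had at least 30 UMIs in at least 10 nuclei, no nucleus with over 20% of them, and no other class with at least 50 nuclei at over 5 times the CPM. It also took up to 4 members per list with the largest conservative fold and members over 2-fold against the list's median. Mitochondrial genes, ribosomal protein genes and genes without a proper symbol were left out. Unnamed clusters are not classes under this rule. A wider check that counts them as classes was added after seeing the data, since several named genes were far higher in an unnamed cluster, and its ratio is given beside such genes. Genes outside the rule are said to be so where they are named. For HGF scaffold over untreated, members of lists are named with values only in part. A few list members that the rule takes are not reported here.

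The ratio and list scripts were tested on simulated counts with 200 changed genes. For scaffold over untreated, intervals over 11480 genes covered the true ratio in 95.8% of cases, 99% of genes changed 2-fold and 100% of those changed 4-fold had intervals excluding 1, and 6% of 100 unchanged lists stood apart. For HGF scaffold over scaffold, with 10756 genes, these values were 96.0%, 97%, 100% and 2%. The simulated counts were Poisson sums over all nuclei, independent between genes, as the intervals assume. Changed genes had at least 100 expected UMIs. These rates therefore check the scripts and do not cover counts clumped in few nuclei, sparse genes of single classes or lists of co-expressed genes.

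Before the data were examined these other settings were chosen: doublet calls kept, at least 500 genes per nucleus, no mitochondrial limit, Leiden resolution 0.5 and 2, each library clustered alone, a marker score per nucleus, nuclei thinned to 500 UMIs, TMM scaling (edgeR 4.0.16 in R 4.3.3), means over nuclei, members with at least 50 UMIs, means over members, and lists without members over 5 times higher in another class. Further settings were added after seeing the data: the 2 doublet removals above, thinning of the libraries to the same oligodendrocyte or fibroblast depth with the floor of 500 UMIs put back, neural nuclei alone as the denominator, and single clusters of a class. Figures were drawn with matplotlib 3.10.9.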

Results

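Nuclei of the lesion epicenter were profiled in 3 libraries, 1 each from untreated injured spinal cord, cord with a scaffold and cord with an HGF-releasing scaffold, so no value has a replicate and every interval covers counting error only. HGF is a growth factor that signals through the receptor tyrosine kinase MET. The untreated library held 2252 nuclei and 5953189 UMIs, the scaffold library 2168 nuclei and 5791715 UMIs, and the HGF scaffold library 906 nuclei and 1450757 UMIs. Median depth per nucleus was 1407.5, 1639 and 1047 UMIs and 942, 1105.5 and 756.5 genes. The HGF scaffold library was therefore the smallest and shallowest.

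Myeloid nuclei (microglia and macrophages) made up 10.1% of untreated nuclei (interval 8.84 to 11.4), 20.7% of scaffold nuclei (19.0 to 22.5) and 32.7% of HGF scaffold nuclei (29.6 to 35.8). Fibroblast nuclei made up 22.2% (20.5 to 24.0), 10.9% (9.65 to 12.3) and 10.1% (90 of 891 nuclei). Neurons were 6.98%, 9.28% and 3.59%, and astrocytes 7.38%, 7.29% and 2.36%, in the same order. Oligodendrocytes were 11.7%, 10.3% and 12.8%, endothelial nuclei 8.67%, 8.12% and 7.97%, OPC 5.83%, 4.57% and 4.60%, and Schwann cell nuclei 4.80%, 2.95% and 1.80%. T or NK cell nuclei were 0.756%, 1.94% and 1.12%, and mural nuclei 0.578%, 0.738% and 0.449%. Skeletal muscle nuclei numbered 6, 0 and 1, and 0 of 2167 scaffold nuclei allows a share of up to 0.170%. With depth matched on oligodendrocytes, a comparison added after seeing the data, the share ratio of scaffold over untreated myeloid nuclei was 10.2, with 31 of 226 untreated myeloid nuclei left above the floor, and with depth matched on fibroblasts it was 2.40. With each library clustered alone, the scaffold over untreated share ratio was 1.45 for oligodendrocytes and 0.257 for Schwann cells, and the HGF scaffold over scaffold ratio 1.73 and 1.78. The HGF scaffold over scaffold ratio for oligodendrocytes was 0.821 with depth matched on them. Clustering anew also changed which clusters took a class name. All shares were taken from nuclei above a floor of 500 UMIs, which a shallower library or a class with little RNA passes less often.

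The myeloid class held a pair of clusters with different leading genes, and different clusters held most of it in different libraries. A cluster led by Lyn, Itgam and Pde4d held 18 untreated, 343 scaffold and 260 HGF scaffold nuclei, or 0.801%, 15.8% and 29.2%. A cluster led by Blnk and Alpk3, with the microglial receptor gene Cx3cr1 among its markers, held 208, 106 and 31 nuclei, or 9.25%, 4.89% and 3.48%. Unnamed nuclei were 20.7%, 23.2% and 22.4% of the libraries. Among them, a cluster led by Ptgds and Igf2 made up 11.4%, 10.5% and 3.25%, and a cluster led by Slc4a4, Foxp2 and Slc26a7 held 184, 130 and 53 nuclei. A cluster led by the macrophage genes Lyz2, Spp1 and Cd74 made up 1.16%, 3.92% and 11.9%. It stayed unnamed on a tie, with the 3 fibroblast markers Col1a1, Col1a2 and Lum and 3 neutrophil markers among its leading genes. A cluster led by the chemokine and cytokine genes Cxcl2, Ccl3 and Il1b made up 0%, 2.72% and 1.35%, where 0 of 2248 untreated nuclei allows up to 0.164%. Its leading genes held 2 neutrophil markers, S100a9 and S100a8, which was under the 3 needed for a name.

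**Figure D1:**
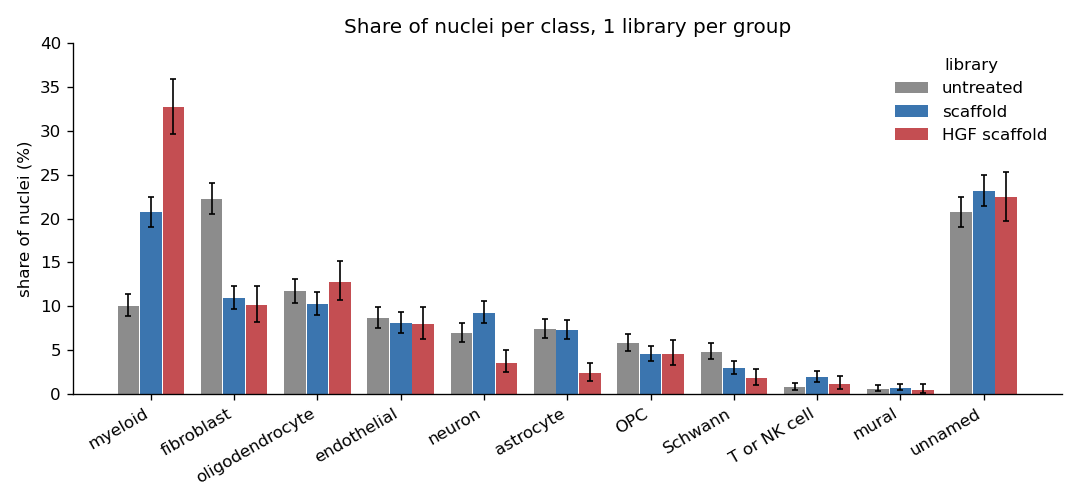
Share of nuclei (%) per class in the untreated, scaffold and HGF scaffold libraries, with bars for 1 library each and lines for exact binomial intervals that cover counting error only. Myeloid shares were 10.1%, 20.7% and 32.7% and fibroblast shares 22.2%, 10.9% and 10.1%.

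Transcripts of Hgf itself, counted from the rat gene, stood at 18.0 CPM (14.7 to 21.7) in all untreated nuclei, 66.9 CPM (60.4 to 73.9) with scaffold and 112.9 CPM (96.0 to 132.0) with HGF scaffold. Met stood at 22.4 CPM (18.7 to 26.5), 115.7 CPM (107.1 to 124.8) and 96.4 CPM (80.8 to 114.2). In myeloid nuclei Hgf was at 97.0, 147.8 and 244.9 CPM, and Met at 25.5, 267.7 and 167.9 CPM, the untreated Met value resting on 5 UMIs. Untreated myeloid nuclei lay mainly in the Blnk and Alpk3 cluster and those of the other libraries in the Lyn and Itgam cluster. Their values therefore compare different clusters, and the sums over all nuclei also follow the myeloid share. Fibroblasts had Hgf at 32.2, 88.8 and 61.6 CPM. Endothelial nuclei had Met at 47.9, 94.5 and 104.4 CPM. Neurons, at 5.12, 29.5 and 12.7 CPM, had less Hgf than myeloid nuclei in every library.

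**Figure D2:**
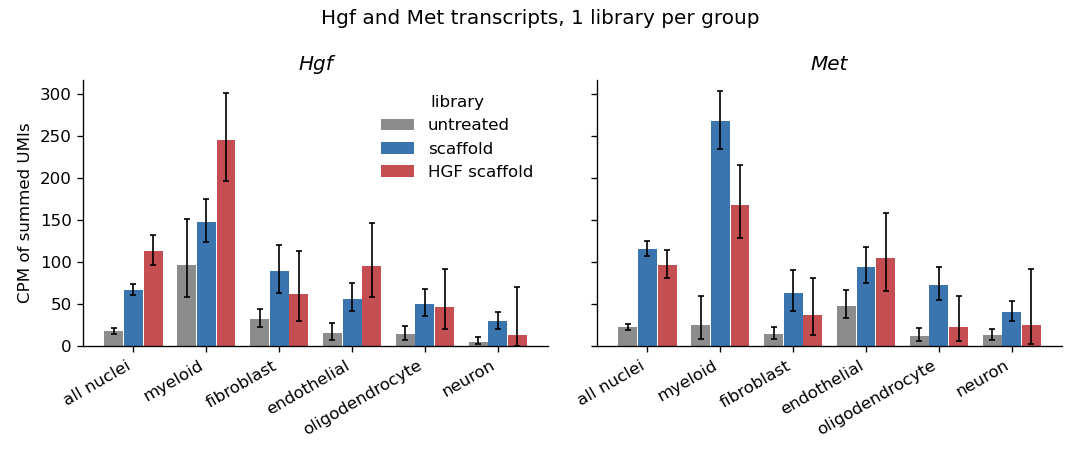
CPM of Hgf and Met summed over all nuclei and over 5 classes in the 3 libraries, with lines for exact Poisson intervals that cover counting error only. Hgf in myeloid nuclei stood at 97.0, 147.8 and 244.9 CPM and Met at 25.5, 267.7 and 167.9 CPM.

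The first comparison, scaffold over untreated, asked what went with an implanted scaffold without HGF. The labels give the untreated library no implantation, so the implanting operation and the material cannot be told apart. Inflammatory and phagocytic genes were higher in the scaffold library's myeloid nuclei, and collagen and other matrix genes were lower in its fibroblasts. Myelin genes were lower in its oligodendrocytes. Genes of glycolysis, the early stress response and T cells were higher over all nuclei. Of 31 lists measured, 9 stood apart above random lists, 11 below, and 11 lay within the middle 95%.

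The pro-inflammatory myeloid list had a median log2 ratio of 1.14 (0.71 to 1.66), at percentile 100, with 12 members higher and 4 lower, and of 2.35 over members with at least 50 UMIs. Nfkbia, an NF-kappaB inhibitor that NF-kappaB itself induces, was 13.2 times as high (5.99 to 36.1) and Il1b, the cytokine IL-1beta, 7.07 times (2.70 to 26.4). Nos2, inducible nitric oxide synthase, had 0 untreated UMIs and was at least 4.39-fold higher. The costimulatory gene Cd86 went the other way, with a ratio of 0.241 (0.126 to 0.466). The phagocytic lipid-handling list stood at 0.79 (0.55 to 1.03; percentile 100; 20 higher, 9 lower), where Spp1 (osteopontin) was 15.7 times as high (10.5 to 24.9), the cathepsin gene Ctsl 9.92 times and the scavenger receptor gene Msr1 6.84 times. Axl, a receptor for dying cells, and the growth factor gene Igf1 were lower in the same nuclei, with ratios of 0.240 and 0.374.

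The alternatively activated list stood at 0.68 (0.38 to 1.38; percentile 99.8; 8 higher, 4 lower), with Arg1, arginase 1, 20.4 times as high (6.91 to 99.5) from 3 untreated UMIs. F13a1 and Gas6 went against it at ratios of 0.359 and 0.487. The median was -0.22 with at least 500 genes per nucleus and 0.0379 with each library clustered alone. The microglia homeostatic list stood at -0.78 (-1.14 to -0.49; percentile 0.10; 1 higher, 9 lower). Sall1, a microglial transcription factor gene, had a ratio of 0.245 (0.159 to 0.378) and the fructose transporter gene Slc2a5 of 0.251, whereas Siglec5 was 11.1 times as high. The antigen presentation list, at 0.27 (-0.09 to 0.71), lay within the random range with 9 members higher and 5 lower, and its class II activator Ciita was at 11.8 times (2.04 to 476.3), from 1 untreated UMI. These myeloid medians compared mainly the Lyn and Itgam cluster of the scaffold library with the Blnk and Alpk3 cluster of the untreated library. Within the Blnk and Alpk3 cluster alone, a comparison added after seeing the data, the pro-inflammatory median was -0.16, the alternatively activated -0.27, the phagocytic 0.22 and the microglia homeostatic 0.11.

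In fibroblasts, the fibrotic matrix list stood at -0.85 (-1.03 to -0.67; percentile 0), with 22 of 24 members lower. Col8a1, a short-chain collagen gene, had a ratio of 0.226 (0.196 to 0.260), the proteoglycan gene Bgn of 0.345 and the type I collagen gene Col1a2 of 0.414 (0.370 to 0.463). The share of fibroblast nuclei had a ratio of 0.492 (0.420 to 0.575), which became 1.22 when each library was clustered alone. Over all nuclei the chondroitin sulfate proteoglycan list stood at -0.26 and lay within the random range. Its member Acan (aggrecan) stood at 2.94 CPM with scaffold against 43.2 CPM untreated, and Chst12, a chondroitin sulfotransferase gene, was 2.85 times as high. The matrix degradation list, at -0.01, also lay within it, although the plasminogen activator gene Plau was 6.56 times as high, Mmp9 3.36 times, Mmp3 2.76 times and Mmp13 2.51 times. The TGF-beta response list stood at -0.27 (percentile 0.76), or -0.06 as a mean over members. Ltbp1, a latent TGF-beta binding protein gene, had a ratio of 0.497, against Junb at 4.93, Tgfbi at 2.57 and the receptor gene Tgfbr1 at 2.26.

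All 20 measured myelin genes were lower than the median gene in oligodendrocytes, with a list median of -0.67 (-0.73 to -0.57; percentile 0.01). Mbp, myelin basic protein, had a ratio of 0.710 (0.678 to 0.744), Mobp of 0.614, the node of Ranvier gene Nfasc of 0.638 and the myelin transcription factor gene Myrf of 0.544. In OPC, the commitment list stood at -0.59 (-0.75 to -0.46; percentile 0.71; 1 higher, 14 lower), with Enpp6, a marker of newly forming oligodendrocytes, at a ratio of 0.530 and the kinase gene Fyn at 0.634. The precursor state list, at -0.38 with 9 of 11 members lower, lay within the random range, with Tnr at 0.631. The oligodendrocyte stress and immune list, at 0.36 (-0.03 to 0.76), lay within it as well, with Cd63 at 3.28 times and the class I subunit gene B2m at 2.41 times. Sterol synthesis genes stood at -0.08 and lay within it too.

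In astrocytes, the reactive list stood at -0.57 (-0.86 to -0.32; percentile 0; 5 higher, 12 lower). The intermediate filament gene Vim had a ratio of 0.358 (0.298 to 0.429), the galectin gene Lgals3 of 0.523 and Cp, ceruloplasmin, of 0.531. The homeostatic list, at -0.18, lay within the random range, with the sodium bicarbonate transporter gene Slc4a4 at a ratio of 0.594. The Schwann cell repair list, at 0.14, lay within it too, with Tnc at a ratio of 0.141 (0.0370 to 0.382). The ependymal cilia list, at -0.56 over 6 measured members, lay within the random range, and its member Armc3 was 2.41 times as high.

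In endothelial nuclei, barrier and transport genes stood at -0.67 (-0.83 to -0.45; percentile 0; 4 higher, 12 lower). Lef1, a transcription factor gene of Wnt signalling, had a ratio of 0.409 (0.344 to 0.486) and the efflux pump gene Abcb1a of 0.584. The list also counts the fenestration gene Plvap as lower, at 0.319, and a lower value of that gene is not a loss of barrier. This median was -0.20 with doublet calls kept, -0.19 without mixed nuclei, 0.02 without the nuclei with the highest Scrublet scores and 0.06 with Leiden resolution 2, and the cause was not tested. Angiogenesis genes over all nuclei stood at -0.27 (-0.40 to -0.05), below the random range, with the angiopoietin receptor gene Tek at 0.588 and its ligand gene Angpt1 at 0.600, against the hypoxia factor gene Hif1a at 2.24 and the growth factor gene Vegfa at 1.78.

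Over all nuclei, axon growth inhibition and guidance genes stood at -0.58 (-0.85 to -0.46; percentile 0), with 21 of 23 members lower. The semaphorin gene Sema3d had a ratio of 0.425, the ephrin gene Efna5 of 0.476, Sema5a of 0.487 and the repellent gene Slit2 of 0.530. Sums over all nuclei also follow the shares of classes, with share ratios of 0.492 for fibroblasts (1.22 with each library clustered alone), 0.615 for Schwann cells (0.257) and 2.06 for myeloid nuclei. Neurotrophic factor genes stood at -0.54 (-0.74 to -0.34; percentile 0.03; 4 higher, 18 lower), with Igf2 at 0.484 and neuregulin 1, Nrg1, at 0.609. Neuron and synapse genes stood at -0.38 (percentile 0.74; 4 higher, 16 lower), with the AMPA receptor gene Gria2 at 0.592 and the synaptic vesicle gene Syt1 at 0.654. That last median was 0.12 when each nucleus was given equal weight, and the share of neuron nuclei had a ratio of 1.33 (1.07 to 1.65), or 1.03 with a marker score per nucleus.

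Hypoxia and glycolysis genes stood at 0.72 (0.57 to 0.83; percentile 100; 18 higher, 4 lower), with the glycolytic regulator gene Pfkfb3 4.28 times as high (3.79 to 4.84), the lactate exporter gene Slc16a3 5.76 times and Ldha, lactate dehydrogenase A, 2.63 times. Immediate early and heat shock genes stood at 0.67 (0.58 to 0.87; percentile 100; 21 higher, 5 lower), with the transcription factor genes Junb at 4.93 times and Atf3 at 3.48 times. Cell cycle genes stood at 0.50 (0.36 to 0.66; percentile 100; 26 higher, 2 lower), with the mitotic kinase gene Aurka at 3.15 times and Top2a at 1.84 times. T cell genes stood at 0.91 (0.65 to 1.26; percentile 99.98), with Icos at 7.42 times and Ctla4 at 4.01 times, and T or NK cell nuclei had a share ratio of 2.56 (1.43 to 4.80). Interferon response genes stood at 0.36 (percentile 99.9; 14 higher, 6 lower), with Ifit3 at 24.2 against 2.02 CPM and Mx2 at a ratio of 0.397. HGF and MET signalling genes stood at 0.34 (0.25 to 0.52; percentile 98.4; 7 higher, 4 lower), with Met 5.18 times as high (4.29 to 6.28), Hgf 3.72 times and the adaptor gene Grb2 1.94 times. These sums also follow the myeloid share, which had a ratio of 2.06 (1.75 to 2.43). Genes of p53 and apoptosis, at 0.11, and mitochondrially encoded transcripts, at -0.12, lay within the random range, with Gadd45b at 4.72 times and mt-Cyb at a ratio of 0.632.

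The named genes of single classes were led by inflammatory genes outside the myeloid class. In scaffold fibroblasts Il1b was 35.8 times as high (11.5 to 180.7) from 3 untreated UMIs, its antagonist gene Il1rn 11.3 times (4.90 to 30.5) and the phagocyte oxidase gene Ncf1 6.61 times (5.03 to 8.76). In oligodendrocytes Il1b was 108.7 times as high (19.0 to 4338) and the survival gene Bcl2a1 55.5 times (9.49 to 2239), each from 1 untreated UMI, and Irg1, which makes itaconate, was at least 39.8-fold higher. In endothelial nuclei the chemokine gene Cxcl2 was at least 95.7-fold higher, Irg1 at least 33.0-fold higher and the lipopolysaccharide-inactivating enzyme gene Aoah 19.0 times as high (12.8 to 29.3). The unnamed Cxcl2 and Il1b cluster held higher CPM of these genes than the classes did, by 83.1 times for Il1b and 56.3 times for Il1rn in fibroblasts, 42.3, 20.9 and 20.1 times for Il1b, Bcl2a1 and Irg1 in oligodendrocytes, and 39.5, 13.9 and 5.14 times for Cxcl2, Irg1 and Aoah in endothelial nuclei. For Ncf1 the unnamed Lyz2 and Spp1 cluster was 5.51 times higher. The myeloid class had 4.40, 2.52 and 3.97 times the CPM of Il1b, Il1rn and Ncf1 in fibroblasts. It had 2.24 and 4.74 times that of Il1b and Bcl2a1 in oligodendrocytes, and 2.855 times that of Aoah in endothelial nuclei. For Irg1 the highest other class was T or NK cells, and no other class had more Cxcl2 than endothelial nuclei. Values without nuclei that hold markers of at least 5 lineages were taken with 0 UMIs set at the floor. The log2 ratio of Cxcl2 in endothelial nuclei was then at least 3.31 in place of at least 6.58. That of Il1b in oligodendrocytes was 4.38 in place of 6.76. Irg1 was then at least at 4.03 in endothelial nuclei and 4.08 in oligodendrocytes, in place of at least 5.04 and 5.31. Aoah in endothelial nuclei was at 4.96 in place of 4.25. With each library clustered alone and 0 UMIs set at the floor, the ratio of Irg1 in oligodendrocytes was 7.45 and that of Bcl2a1 21.7. In fibroblasts, Il1rn had a ratio of 3.95 without the nuclei with the highest Scrublet scores and Il1b of 14.7 with each nucleus given equal weight. Myeloid nuclei had Pde4d, itself a leading gene of the Lyn and Itgam cluster, at 13.7 times (11.8 to 16.1) and the lipoprotein-associated phospholipase gene Pla2g7 at 12.6 times (7.72 to 22.2).

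Among genes lower in single classes, fibroblasts had Acan at a ratio of 0.0644 (0.0173 to 0.168), Sema3d at 0.151 (0.0990 to 0.220) and Col8a1 at 0.226. Oligodendrocytes had the calcineurin regulator gene Rcan2 at 0.387 (0.336 to 0.443), Xkr4 at 0.391 and the collagen gene Col23a1 at 0.376. Endothelial nuclei had P3h2, a collagen prolyl hydroxylase gene, at 0.162 (0.0977 to 0.258), Fndc1 at 0.177 and Pgm5 at 0.283. Fndc1 was at 0.445 without mixed nuclei and had 4.53 times as high a CPM in fibroblasts. Pgm5 was at 0.437 without the highest Scrublet scores. With Leiden resolution 2, Acan in fibroblasts was at 0.109 and Sema3d at 0.240. Myeloid nuclei had Nell2 at 0.0561 (0.0261 to 0.111), Alpk3 at 0.104 and the sialomucin gene Cd34 at 0.0907, and Alpk3 is a leading gene of the myeloid cluster that held most untreated myeloid nuclei. Within that cluster alone the ratios were 0.232 for Nell2, 0.578 for Alpk3 and 0.443 for Cd34, and 4.76 for Pde4d, 9.70 for Spp1 and 5.96 for Pla2g7, and Spp1 in the class was at 4.48 with at least 500 genes per nucleus. Nell2 had 3.925 times as high a CPM in neurons as in myeloid nuclei, and Cd34 3.26 times in endothelial nuclei.

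The comparison of HGF scaffold over scaffold asked what went with HGF release. Antigen presentation genes were higher in HGF scaffold myeloid nuclei and matrix genes were higher in HGF scaffold fibroblasts. Genes of the neuron and neurotrophic lists were lower over all nuclei, and the share of neuron nuclei was lower. Of 31 lists measured, 7 stood apart above random lists, 5 below, and 19 lay within the middle 95%.

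In myeloid nuclei, mostly of the Lyn and Itgam cluster in both libraries, the antigen presentation list stood at 0.98 (0.66 to 1.28; percentile 100), with 16 of 18 members higher. The class II gene RT1-Bb was 7.37 times as high (2.80 to 22.7), and the class I genes RT1-A1, RT1-CE5 and RT1-A2 were 3.28 times (2.45 to 4.40), 3.02 times and 2.77 times as high. The RT1 genes are similar, polymorphic copies, so UMIs of single members are uncertain. Within the Lyn and Itgam cluster alone, a comparison added after seeing the data, the median was 1.07. The alternatively activated list stood at 0.26 (0.11 to 0.41; percentile 98.9; 10 higher, 2 lower), or 0.45 with each library clustered alone, with the mannose receptor gene Mrc1 2.55 times as high (2.10 to 3.11) and Tgfb1 at a ratio of 0.626. The pro-inflammatory list, at 0.10, lay within the random range, with Cxcl2 at a ratio of 0.313 and Ccl3 at 1.91. The phagocytic list, at 0.07, and the microglia homeostatic list, at -0.24, also lay within it, with the lipid scavenger receptor gene Cd36 at 2.87 times, Spp1 at a ratio of 0.677 and Sall1 at 0.461. The share of myeloid nuclei had a ratio of 1.58 (1.36 to 1.83).

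In fibroblasts, the fibrotic matrix list stood at 0.82 (0.51 to 1.09; percentile 100; 17 higher, 4 lower). The smooth muscle actin gene Acta2 was 6.76 times as high (2.83 to 17.9), from 19 HGF scaffold UMIs. Acta2 marks myofibroblasts but was also among the markers of the mural cluster, and RNA of mural cells was not tested as its source. Col8a1 was 3.11 times as high (2.58 to 3.76), Tnc 3.06 times and the fibrillar collagen gene Col5a2 2.66 times. The fibroblast class held 90 HGF scaffold nuclei against 237, and its share had a ratio of 0.924 (0.716 to 1.18), which was 1.51 without a mitochondrial limit and 0.661 at Leiden resolution 0.5. The limit itself removed 4 untreated nuclei, but without it a cluster of 277 nuclei stayed unnamed with 2 markers. At resolution 0.5 a cluster of 493 nuclei took the fibroblast name. The chondroitin sulfate proteoglycan list, at 0.05, lay within the random range, with versican, Vcan, at 1.40 times. Matrix degradation genes stood at 0.11 and lay within it, with Mmp13 at 2.38 times, Mmp9 at 2.38 times and Mmp3 at 2.25 times. TGF-beta response genes, at -0.12, lay within it as well, with Tgfbr1 at 1.41 times.

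Neuron and synapse genes stood at -1.34 (-1.52 to -0.97; percentile 0), with all 21 measured members lower. The NMDA receptor gene Grin2b had a ratio of 0.284 (0.215 to 0.368), the GABA receptor gene Gabrb2 of 0.172, Gria1 of 0.338 and Syt1 of 0.360. Neurons were 3.59% against 9.28% of nuclei, a ratio of 0.387 (0.258 to 0.564). The neurotrophic factor list stood at -0.72 (-1.14 to -0.47; percentile 0; 3 higher, 16 lower). Its member Nrg1, also a leading gene of the neuron cluster, was at 0.349 (0.312 to 0.389) and its member Fgf14 at 0.341. These sums over all nuclei also follow the lower share of neurons, so a change in trophic supply cannot be read from them. The axon guidance list, at -0.04, lay within the random range, with Slit1 at 0.313 and Efna5 at 1.48.

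Astrocyte lists were read in all nuclei here, because the HGF scaffold library held 21 astrocytes, and the share of astrocytes had a ratio of 0.323 (0.195 to 0.511), or 0.717 (0.406 to 1.23) with depth matched on oligodendrocytes. Homeostatic genes stood at -0.44 (-0.71 to -0.16; percentile 0.03; 4 higher, 12 lower), with the glutamate transporter gene Slc1a2 at a ratio of 0.405 and the water channel gene Aqp4 at 0.529. Reactive genes stood at 0.24 (0.05 to 0.36; percentile 99.97; 17 higher, 8 lower), with Tnc at 2.27 times and the interferon-induced gene Gbp2 at 2.34 times, whereas the astrocyte filament gene Gfap had a ratio of 0.491 (0.431 to 0.557) and Aspg of 0.441. The reactive median was -0.02 when each nucleus was given equal weight. Schwann cell repair genes, also read in all nuclei, stood at -0.27 (percentile 1.91), with Igfbp2 at 0.448 and Tnc at 2.27. Igfbp2 is a leading gene of the unnamed Ptgds and Igf2 cluster, whose share ratio was 0.309 (0.203 to 0.456). Tnc, in this list and the reactive list, is a leading gene of the largest fibroblast cluster. Schwann cells had a share ratio of 0.608 (0.328 to 1.06), and a change within them cannot be read from these sums.

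Myelin genes in oligodendrocytes stood at 0.35 (0.24 to 0.52; percentile 99.2), with 18 of 20 members higher, among them Nfasc at 1.79 times (1.51 to 2.11), Tspan2 at 1.54 times and Mobp at 1.46 times. This median was 0.13 with each library clustered alone and 0.20 with doublet calls kept. Sterol synthesis genes, at -0.05, and stress and immune genes, at 0.08, lay within the random range, with Hmgcs1 at a ratio of 0.433 (0.113 to 1.19) and the glucocorticoid-induced gene Fkbp5 at 1.59. The lists of OPC, read in all nuclei, lay within it at -0.13 for the precursor state and 0.06 for commitment, with Dscam at 0.504, Matn4 at 2.23 and Tcf7l2 at 1.80.

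Over all nuclei, cell cycle genes stood at 0.45 (0.16 to 0.62; percentile 100; 23 higher, 4 lower), with the cyclin gene Ccna2 4.16 times as high (1.64 to 10.6) and Cenpf 2.18 times. Their median was 0.14 when each nucleus was given equal weight. Interferon response genes stood at 0.32 (0.11 to 0.47; percentile 99.96; 15 higher, 5 lower), with Gbp5 at 2.30 times. Immediate early and heat shock genes stood at -0.18 (percentile 2.19; 9 higher, 17 lower), with Nr4a3 at 0.446 and Klf6 at 1.69, and at -0.51 when each nucleus was given equal weight. HGF and MET signalling genes, at -0.08, lay within the random range with Hgf 1.69 times as high (1.39 to 2.04) and Met at a ratio of 0.833 (0.687 to 1.004). Angiogenesis genes, at 0.12, lay within it with Angpt1 at 1.69 times, Pecam1 at 1.65 times and Pdgfb at 0.426, as did endothelial barrier genes, at 0.09, with the tight junction gene Tjp1 at 1.74 times. Hypoxia and glycolysis (0.06), T cell (-0.20), ependymal cilia (-0.05), p53 and apoptosis (0.11) and mitochondrially encoded (0.09) lists lay within it too, with Aldoa at 1.52 times, Skap1 at 0.730, Spag16 at 1.81, Gadd45b at 0.482 and mt-Nd4l at 0.497.

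The genes named in single classes for HGF scaffold over scaffold included Slfn3, a Schlafen family gene, in both myeloid nuclei at 4.57 times (3.91 to 5.34) and oligodendrocytes at 2.37 times (1.96 to 2.86). Myeloid nuclei also had the mitochondrial thymidine kinase gene Tk2 at 3.88 times (2.11 to 7.30), the transcription factor gene Bcl11a at a ratio of 0.176 (0.0626 to 0.398) and the activation gene Cd83 at 0.239 (0.111 to 0.457). Cacfd1 had 0 UMIs in them and was at least 6.24-fold lower. Bcl11a had 3.86 times as high a CPM in neurons as in myeloid nuclei. Oligodendrocytes had Prex2 at 2.49 times (1.97 to 3.13) and the glycerol phosphate dehydrogenase gene Gpd1 at 3.31 times (1.94 to 5.59). They had the hexokinase gene Hk2 at a ratio of 0.132 (0.0268 to 0.398) from 3 UMIs, the antioxidant regulator gene Nfe2l2 at 0.232 and Rgs1 at least 2.94-fold lower. Hk2 was at 0.334 with each library clustered alone. Without mixed nuclei Rgs1, with 0 HGF scaffold UMIs set at the floor, was at most at 0.577. Fibroblasts had Zfhx4 at 5.44 times (3.51 to 8.55), Efna5 at 3.83 times and the collagen gene Col11a1 at 3.71 times. They had Adgrb3 at 0.234 (0.144 to 0.361), and Pon3 and Cobl each at least 3.98-fold lower, although Pon3 was higher, with a log2 ratio of 0.49, when each library was clustered alone. Within the largest fibroblast cluster alone Cobl, with 0 HGF scaffold UMIs set at the floor, was at most at 0.570. Adgrb3 had 4.91 times as high a CPM in OPC as in fibroblasts, and Pon3 3.98 times in myeloid nuclei. Endothelial nuclei had Nxph1 at 2.93 times, Dysf at 2.97 times and the protocadherin gene Pcdh17 at 3.25 times, with Dysf at 1.94 times at Leiden resolution 2 and Pcdh17 at 1.77 times with each nucleus given equal weight. They had Trpm3 at 0.152 (0.124 to 0.186), Cxcl2 at 0.0938 (0.0402 to 0.187) and Ptgds at 0.192. Without mixed nuclei, which numbered 311 in the scaffold library against 42, the ratio was 0.550 for Trpm3, 0.387 for Cxcl2 and 1.61 for Nxph1. With each library clustered alone Cxcl2 was at 0.783 and Ptgds at 0.571. Trpm3 had 4.12 times as high a CPM in fibroblasts as in endothelial nuclei, Nxph1 4.80 times in OPC and Ptgds 3.93 times in astrocytes. The unnamed Cxcl2 and Il1b cluster had 39.5 times as much Cxcl2, and the unnamed Ptgds and Igf2 cluster 20.3 times as much Ptgds, as the endothelial class. The unnamed Lyz2 and Spp1 cluster had 6.02 times as much RT1-A1 as the myeloid class, and the Cxcl2 and Il1b cluster 5.93 times as much Slfn3 as the oligodendrocyte class.

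**Figure D3:**
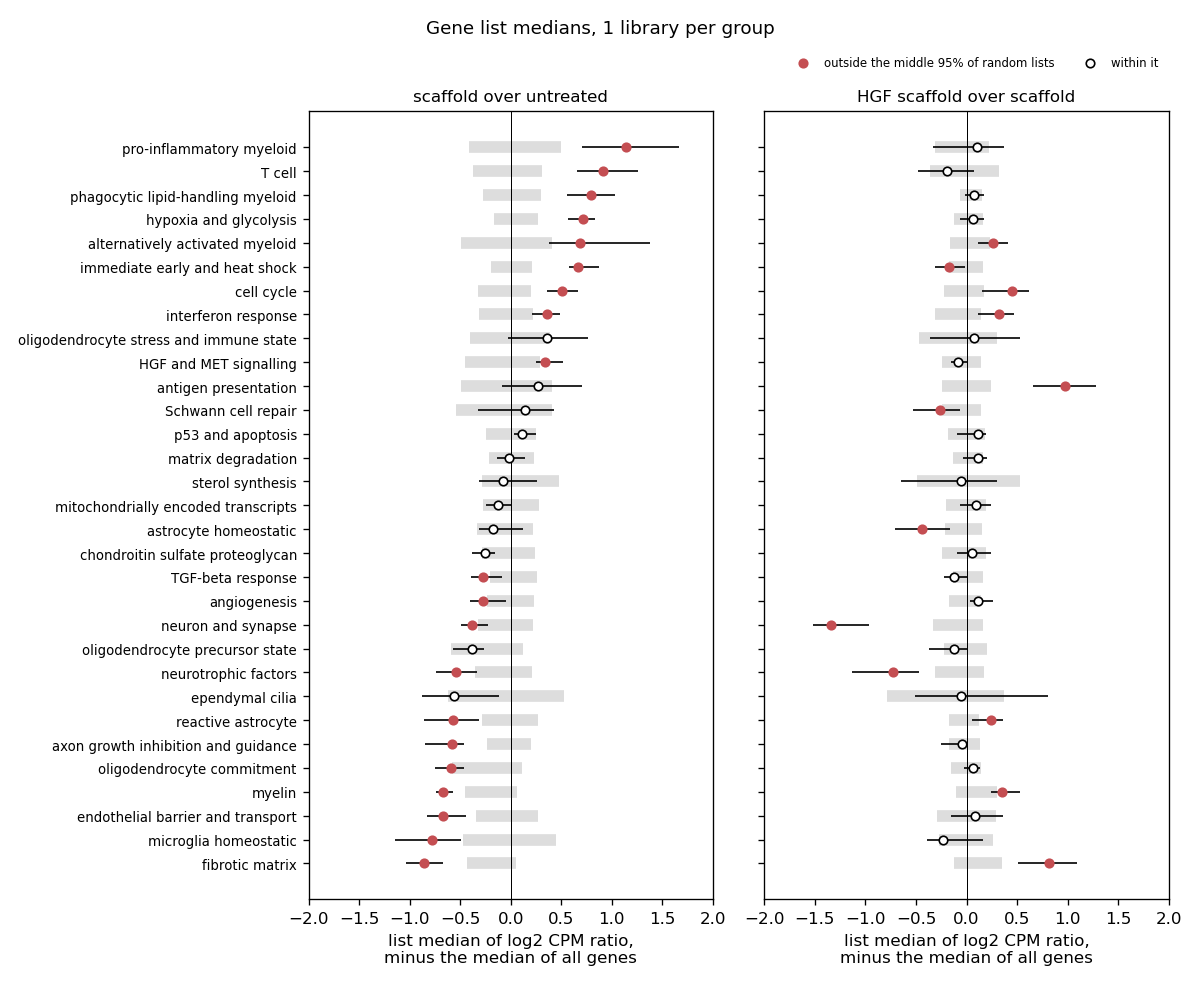
Median log2 CPM ratio of each of 31 gene lists minus the median of all genes, for scaffold over untreated and HGF scaffold over scaffold, with lines for Poisson resampling intervals and grey bars for the middle 95% of 10000 matched random lists. The fibrotic matrix list lay at -0.85 and then at 0.82, and the neuron and synapse list at -0.38 and then at -1.34.

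The third comparison, HGF scaffold over untreated, shares its libraries with the other two and adds no independent evidence. Myeloid nuclei were again higher in share, with a ratio of 3.25 (2.72 to 3.88), and fibroblasts lower, at 0.454 (0.359 to 0.569). The other settings were not run for this comparison. With each library clustered alone, the fibroblast ratio was 1.22 for scaffold over untreated and 1.42 for HGF scaffold over scaffold. The lower fibroblast share therefore depends on the clustering. Of 31 lists, 9 stood apart above random lists, 10 below, and 12 lay within the middle 95%. The fibrotic matrix list in fibroblasts lay within it at -0.06 (-0.23 to 0.06; 10 higher, 14 lower). Acta2, also a mural marker, was 5.13 times as high (2.69 to 9.57), from 19 HGF scaffold and 27 untreated UMIs. Lists that stood apart above were pro-inflammatory (1.74), alternatively activated (1.37), antigen presentation (1.01) and phagocytic (0.83) in myeloid nuclei, and cell cycle (0.96), hypoxia and glycolysis (0.88), T cell (0.85), interferon response (0.67) and immediate early (0.60) in all nuclei. Medians in myeloid nuclei again compared mainly different clusters, the Lyn and Itgam cluster (260 HGF scaffold nuclei) with the Blnk and Alpk3 cluster (208 untreated nuclei). Lists that stood apart below were microglia homeostatic in myeloid nuclei (-1.01), barrier and transport in endothelial nuclei (-0.41), and, in all nuclei, neuron and synapse (-1.58), neurotrophic factors (-1.30), astrocyte homeostatic (-0.87), OPC precursor state (-0.85), Schwann cell repair (-0.82), axon guidance (-0.78), TGF-beta response (-0.42) and chondroitin sulfate proteoglycan (-0.35). The lists that lay within were fibrotic matrix, HGF and MET signalling (0.36), reactive astrocyte (0.23), matrix degradation (0.01), angiogenesis (-0.08), myelin (-0.27), sterol synthesis (0.10), oligodendrocyte stress (0.31), commitment (-0.39), ependymal cilia (-0.07), p53 and apoptosis (0.29) and mitochondrially encoded transcripts (0.02).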

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

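Each group holds 1 library, so animal, surgery, dissection and library preparation cannot be told apart from treatment, and intervals cover counting error only. No paired analysis was possible because each group holds 1 library. Shares and medians below are for scaffold over untreated unless HGF scaffold over scaffold is named. The settings with depth matched, the highest Scrublet scores removed, mixed nuclei removed, neural nuclei alone and a single cluster were chosen after seeing the data, and the others before the data were examined. The direction of the myeloid share was the same in every setting. Where a value moved, the cause was not tested. Settings that clustered the nuclei anew also changed which clusters took a class name, so shares in them follow the naming too. TMM scaling cannot move a list median that is centred on all genes, so it tests nothing here.

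With at least 500 genes per nucleus, the share ratio of myeloid nuclei was 2.55 and of fibroblasts 0.721, the fibroblast ratio for HGF scaffold over scaffold was 1.19, the alternatively activated median was -0.22, and median depth was 1672 UMIs untreated, 1769 with scaffold and 1233 with HGF scaffold. With a marker score per nucleus, the share ratios were 3.34 for myeloid nuclei, 0.707 for endothelial nuclei and 1.03 for neurons, and 0.938 for oligodendrocytes in HGF scaffold over scaffold. With doublet calls kept, the fibroblast ratio was 0.634, and 1.41 for HGF scaffold over scaffold. The endothelial ratio was then 0.737, and the medians were -0.20 for endothelial barrier genes, 0.20 for alternatively activated genes, and -0.48 for myelin, or 0.20 for myelin in HGF scaffold over scaffold. Without a mitochondrial limit the fibroblast ratio was 0.699, and 1.51 for HGF scaffold over scaffold. With Leiden resolution 0.5 it was 0.630, and 0.661 for HGF scaffold over scaffold. With resolution 2 the endothelial ratio was 0.692 and the barrier median 0.0574. With nuclei thinned to 500 UMIs the fibroblast ratio was 0.733 (0.7325) and the endothelial ratio 0.712.

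With each library clustered alone, share ratios were 1.22 for fibroblasts, 1.45 for oligodendrocytes and 0.257 for Schwann cells, and in HGF scaffold over scaffold 1.19 for myeloid nuclei, 1.42 for fibroblasts, 1.73 for oligodendrocytes and 1.78 for Schwann cells. Medians were -1.22 for fibrotic matrix, 0.0379 for alternatively activated genes, -0.79 for myelin and -0.77 for oligodendrocyte commitment. In HGF scaffold over scaffold they were 0.45 for alternatively activated genes and 0.13 for myelin, and Pon3 in fibroblasts had a log2 ratio of 0.49. Naming differed in this setting, where an untreated cluster of 145 nuclei stayed unnamed for mixed markers and high UMIs. A scaffold cluster of 50 nuclei with 2 Schwann cell markers among its top 10 genes also stayed unnamed.

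With depth matched on oligodendrocytes, share ratios were 10.2 for myeloid nuclei (2.40 with depth matched on fibroblasts), where 31 untreated myeloid nuclei were left above the floor, 0.405 for fibroblasts and 0.726 for astrocytes. In HGF scaffold over scaffold they were 1.32 for myeloid nuclei, 1.22 for fibroblasts, 0.821 for oligodendrocytes and 0.717 for astrocytes, the last being 0.331 with depth matched on fibroblasts. With the highest Scrublet scores removed, the fibroblast ratio was 0.732 (0.7316), and 1.42 for HGF scaffold over scaffold, the endothelial ratio was 0.697, and the medians were -1.22 for fibrotic matrix and 0.0239 for endothelial barrier genes. With mixed nuclei removed, the endothelial ratio was 0.726, and the medians were -0.19 for endothelial barrier genes, -0.56 for myelin, -0.23 for neuron and synapse genes, and -0.39 for immediate early genes in HGF scaffold over scaffold. Among neural nuclei alone, oligodendrocytes had a ratio of 1.67 in HGF scaffold over scaffold. In the Blnk and Alpk3 myeloid cluster alone, the medians were 0.11 for microglia homeostatic, 0.22 for phagocytic, -0.16 for pro-inflammatory and -0.27 for alternatively activated genes.

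With each nucleus given equal weight, the medians were 0.23 for HGF and MET signalling, -0.39 for endothelial barrier genes and 0.12 for neuron and synapse genes, and in HGF scaffold over scaffold -0.0196 for reactive astrocyte, 0.14 for cell cycle and -0.51 for immediate early genes. As means over members, TGF-beta response stood at -0.0610 and myelin at -0.74. With at least 50 UMIs per member the pro-inflammatory median was 2.35.

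Some settings gave no value: T or NK cell and mural shares with each library alone, mural shares at resolution 0.5 and with the highest Scrublet scores removed, and T or NK cell shares after thinning. The Lyn and Itgam cluster held too few untreated nuclei, and the Blnk and Alpk3 cluster too few HGF scaffold nuclei, for single-cluster medians. Schwann cell repair with each library alone and ependymal cilia with at least 50 UMIs gave none either.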

Other observations

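RT1-A1 and Slfn3 were higher in the HGF scaffold than in the scaffold library in each of the 4 classes compared. The class I gene RT1-A1 was 3.68 times as high over all nuclei (3.29 to 4.11), with RT1-A1 at 3.08 times in endothelial nuclei, 1.99 in fibroblasts and 1.98 in oligodendrocytes. Slfn3, a Schlafen family gene, was 2.56 times as high in endothelial nuclei and 2.22 times in fibroblasts. Cacfd1, a calcium channel flower domain gene, had 4 UMIs in all nuclei of the HGF scaffold library against 179, a ratio of 0.0931 (0.0251 to 0.242). The values of RT1-A1 and Slfn3 across classes and of Cacfd1 over all nuclei were picked after the results were seen. RT1-A1 is polymorphic, and inherited differences between the animals were not tested.

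All tests in this part were chosen only after the patterns were seen, and for inflammatory and fibrotic matrix genes the bounds were set before the values of the tests were known. The astrocyte share was lower in the HGF scaffold library than in the scaffold library, a ratio of 0.323. With the libraries thinned to the same oligodendrocyte depth it was 0.717 (0.406 to 1.23), but with the same fibroblast depth 0.331 (0.199 to 0.524), so the part of depth stays open. Neurons had ratios of 0.272 (0.181 to 0.397) and 0.379 (0.252 to 0.552) after these thinnings. In them nuclei kept their classes and only the floor acted. Scaffold neurons were deep, at a median of 4372 UMIs, and 92.0% of them passed the floor after oligodendrocyte matching. The thinning could therefore hardly raise the ratio, and it cannot decide on depth. Among neural nuclei alone the ratio was 0.521 (0.347 to 0.760), which argues against less cord in the piece as the whole cause. The mix of gray and white matter in the piece was not tested.

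Inflammatory genes such as Il1b, Cxcl2 and Irg1 were higher in non-myeloid classes of the scaffold library, and free RNA from myeloid cells could be the source. Free RNA would give similar folds in a class and in all nuclei, and the median of fold in the class over fold in all nuclei was 0.770 with genes at 0 untreated UMIs set at their bound. Of 9 values 3 are such bounds, so the median lies anywhere from 0.770 to 2.34, and that of the other 6 was 1.58 (range 0.656 to 5.07), which leaves free RNA open. Without mixed nuclei 0.789 of the median log2 fold was kept, or 0.969 over those 6, which leaves mixed nuclei open. Some of these folds rest on 1 untreated UMI.

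Fibrotic matrix genes were lower in scaffold fibroblasts and higher in HGF scaffold fibroblasts. Within the largest fibroblast cluster alone the medians were -0.93 and 0.88, or 1.09 and 1.08 of those in the whole class. Without mixed nuclei they were -0.96 and 0.92, or 1.13 and 1.13. These values argue against mixed nuclei, and against the mix of the fibroblast clusters found at resolution 1, as the cause. A different mix of states inside the largest cluster was not tested, and list members such as Col1a1 and Col8a1 are among its leading genes. With 1 library per group, differences between animals stay open and an effect of treatment remains a hypothesis.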
